A study of Mus musculus with 10 samples.

How the data were processed

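RNA from FACS-sorted mammary epithelial cells of female mice was extracted with TRIzol, amplified to double-stranded cDNA with a kit made for small inputs (Ovation RNA-seq V2) and made into barcoded libraries (Ovation Ultralow DR), per the labels' protocols. The 10 libraries were grouped by their titles into 5 groups of 2. Per the submitters' processing notes, the tools were STAR and DESeq and the genome build was mm9. Versions, the read counter, the annotation, strand settings and the DESeq options are not given in the sources used here.

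The authors deposited 6 comparison tables of 24000 genes. Per the file headers, each gives the mean signal of either group (normalised read counts as DESeq scales them), their ratio (fold change), its log2 and a p-value. The deposited log2 column was not used, because a part of it holds spreadsheet errors, and log2 folds were computed from the means. The deposited p-values are unadjusted, and cover the 13698 to 14986 genes with a count in at least 1 column. The deposited ratio runs first group over second in 2 tables and second over first in 4, so every fold was recomputed from the means in a stated direction. Spreadsheet date conversion had replaced 27 symbols and 4 were duplicated, and those genes were left out of the results per gene while kept in totals and adjustments. The files hold no columns per library (0 per-sample columns), and 0 columns of other origin were found.

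Every mean in the authors' deposited tables is a whole multiple of 1 step per column, for 100% of values within 0.01 of a count, so whole read counts were recovered by dividing by that step. The steps of the columns in a table multiply to 1, as DESeq size factors of exactly 2 columns do. The deposited p-values therefore come from a comparison of 1 column with 1 column and contain no spread between replicates, and the files do not say whether a column pools both libraries of its group or holds 1 of them. All tests compare those columns and not the conditions. Each column was followed through the tables by its counts, which gave 5 distinct columns and showed that the names of the basal columns conflict.

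Calls used the authors' DESeq p-values with Benjamini-Hochberg adjustment over all genes that have one, at 0.05. The plan had assumed adjusted p-values in the files and this replaced them. Intervals of folds are exact binomial (Clopper-Pearson) 95% intervals of the split of a gene's reads between the columns. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A fold against 0 counts was computed against a floor of 3 counts and is given as a lower bound, which leaves out the counting error of the other column (for Lrrn2 the bound is 50.5 and the interval starts at 40.6). Levels across tables use the recovered counts with median-of-ratios factors over the 5 columns. Column totals ran from 2036681 to 3840462 counts, and genes near 0 in either column have wide intervals.

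Named genes followed a rule: Bptf first, then up to 10 genes with the largest fold in each direction among those past 0.05 with a mean value of at least 50 and both means above 0, passing over predicted genes and small RNAs, then up to 4 members per list among those past the threshold. Other genes, named with values only or for small counts of calls, were chosen after their values were seen. The groups of genes were 35 lists with 607 entries, of which 3 matched no symbol. The lists, this rule and the first set of other settings were fixed before the data were examined. For each list the number past the test is given over all genes and adjusted over the list alone, with the median of log2 folds of values plus 1 and its percentile among 10000 random lists of the same size drawn from the same 10 bins of mean expression. Random lists were drawn gene by gene. Lists of genes that vary together can therefore reach extreme percentiles, which describe these columns and are not tests. A planned Fisher test of the lists and of overlaps is not printed, because p-values across genes of single columns do not measure replication. The difference of the genotype effect between cell types used log2 folds with standard errors derived from the deposited p-values and is approximate. Changing the scale shifts all log2 folds of a comparison by 1 constant, given in the section on processing choices, and list medians stated with a direction exceed it.

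Gapdh, Eno1, Pgk1, Hmgcs1 and Idi1 were near 0 in every column, and no difference in them was read. The reason was not tested. Coordinates are not given, since the reference used here is of another build than mm9. Steps across many genes were tested on simulated counts with 200 changed genes per comparison. With counting error alone, intervals covered 94.89% to 95.95% of true folds and the exact binomial test made 4 to 8 false calls per comparison. With an added dispersion of 0.16 the intervals covered 30.01% to 32.61% and false calls numbered 4308 to 5426, so counting intervals understate the spread that independent libraries would show. Alternatives were stricter and looser thresholds, other adjustments, minimum means, other scales (totals without Rn45s and edgeR's TMM), an exact binomial test and an edgeR exact test of the recovered counts with an assumed dispersion of 0.16. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.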

Results

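RNA was sequenced from epithelial cells sorted from the mammary glands of female mice that were wild type or knockout for Bptf. Bptf is the largest subunit of the NURF chromatin remodelling complex, and the series asks what it does for open chromatin and for the renewal of mammary stem cells. All mice had received tamoxifen, 15 mg per kg in total, before the cells were taken. The 10 libraries formed 5 groups of 2, namely luminal cells of each genotype, myoepithelial (basal) cells of each genotype, and a population labelled Bsecs, which the labels name for the knockout alone and do not spell out. The deposited tables held 1 column of mean values per group and no value per library, so no difference in this section has a replicate check and every test compares sorted populations as sequenced, not conditions. Counts recovered from those means summed to 2729006 in WT luminal cells, 3840462 in the column labelled KO luminal, 3659403 in Bsecs, and 2036681 and 2359861 in the basal columns. Between 11791 and 13957 genes were detected per column. The ribosomal RNA precursor Rn45s took 32.2% of the Bsecs counts, 15.9% of KO luminal, 10.6% of WT luminal, 16.2% of the smaller basal column and 9.76% of the larger basal column.

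The basal columns carried opposite genotype names in different tables. The column of 2036681 counts was headed KO in the table that compares basal cells and WT in the table that compares Bsecs with WT basal cells, and the column of 2359861 counts had the reverse. With the headers as given, the log2 folds of the 3 tables that join Bsecs and the basal columns closed to within 0.1 of their median for 4.18% of 5646 genes. With the names in the basal table exchanged they closed for 100% of them, as those of the luminal tables did for 6865 genes with no exchange. This closure follows from each column holding the same counts in every table. It would also hold with the names in both Bsecs tables exchanged, so it does not show which headers of the basal columns are wrong. These columns are therefore called the smaller and the larger basal column, and no direction between them is read as an effect of the knockout. The luminal column headed KO had a second conflict, since 1 label of its libraries names wild-type mice as the source and another the knockout.

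Bptf itself was read in all 5 columns, with 420 counts in the smaller basal column, 780 in the larger, 640 in WT luminal cells, 1018 in the column labelled KO luminal and 645 in Bsecs. Its normalised value in the KO luminal column was 1.27 times that in WT luminal cells (95% counting interval 1.15 to 1.40). The smaller basal column had 0.754 times the value of the larger one (0.668 to 0.850). Bsecs had 0.910 times the larger basal column (0.818 to 1.01), 1.21 times the smaller (1.07 to 1.37), 0.950 times KO luminal cells (0.860 to 1.05) and 1.24 times WT luminal cells (1.11 to 1.39). These small ratios rest on the scale. With totals without Rn45s in its place the log2 fold of Bsecs over WT luminal cells turned from 0.31 to -0.01, and that over the smaller basal column went from 0.27 to 0.08. The p-values of the authors' deposited tables for Bptf lay between 0.618 and 0.959, and none passed adjustment. Counts over a whole gene do not check a deletion that removes some of its exons, so these values neither support nor contradict the genotype labels.

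The luminal comparison asks what separates Bptf knockout from wild-type luminal cells. Dmbt1, a secreted mucin-like protein of epithelial surfaces, rose from 138 to 11689 counts in the column labelled KO luminal, 67.5-fold (57.1 to 80.4). Sfn (14-3-3 sigma, a keratinocyte and stress protein) rose 11.5-fold (10.5 to 12.6), Apobec3, a cytidine deaminase that restricts retroviruses, 13.7-fold (9.43 to 20.7), and Col17a1, the hemidesmosome collagen, from 2 to 184 counts, 73.3-fold (20.01 to 610). Pnpla8 had 148 counts against 1 (118-fold, 20.8 to 4689). Mad2l1, a spindle checkpoint protein, fell 8.68-fold (7.38 to 10.3), Rgs4, a regulator of G protein signalling, 19.3-fold (11.8 to 33.6), the neutrophil-associated calcium binder S100a8 32.5-fold (15.4 to 81.9) and Psapl1 35.8-fold (16.1 to 98.8). In all, 8 genes were higher and 5 lower among 14736 at an adjusted p under 0.05, by Benjamini-Hochberg adjustment of the DESeq p-values in the authors' deposited table, and 551 (3.74%) had an unadjusted p under 0.05. The rest were the predicted genes and small RNA 5430419D17Rik, Snord32a and Gm6682, and Lrrn2, which had 190 counts against 0 (at least 50.5-fold higher). The adjusted p was 1.95e-06 for Dmbt1 and 0.0433 for Mad2l1, from the p-values of the authors' deposited table.

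Genes of basement membranes leaned to the column labelled KO luminal. Of 18 measured members of that list 1, Col17a1, passed over all genes and 2 adjusted over the list alone, and the list's median log2 fold of 1.02 stood at percentile 99.99 of 10000 random lists matched on expression. Lamc1 was at 2.98-fold (2.58 to 3.45) in that column. The basal identity list had 0 of 23 members past the test over all genes, 1 lower adjusted over the list alone, and a median of 1.24 at percentile 99.9. Krt14 was at 4.40-fold (3.28 to 5.99) and Krt17 at 4.34-fold (3.45 to 5.52) in the KO luminal column, while the endopeptidase Mme was lower, at 6.59-fold (5.24 to 8.37). Levels of these keratins stayed below those of basal cells on the common scale, with Krt14 at 215 normalised counts in KO luminal cells, 2091 in the larger and 7582 in the smaller basal column, and Krt17 at 343, 2043 and 7568. Col17a1 was likewise at 133 in KO luminal and 1.79 in WT luminal cells, and at 1058 and 2635 in the larger and smaller basal columns. Sparc, at 2379 and 1933 in those basal columns, went the other way, with 2.89 in KO luminal and 34.8 in WT luminal cells. Whether basal cells entered the luminal sorts was not tested. Milk and alveolar genes lay the other way in part. None of 19 members passed over all genes and 4 were lower adjusted over the list alone, while the list's median of -0.03 was at percentile 39.3. The casein Csn3 was at 5.48-fold (5.10 to 5.90), the lipid droplet protein Plin2 at 5.16-fold (3.83 to 7.06), butyrophilin Btn1a1 at 4.93-fold (3.99 to 6.13) and lactoferrin Ltf at 4.29-fold (4.02 to 4.57) lower in the KO luminal column than in WT. Interferon response genes had a median of 0.95 at percentile 99.96 with 0 of 23 past either adjustment (over all genes or adjusted over the list alone), among them Rtp4 at 4.75-fold (3.46 to 6.64) and Stat2 at 3.36-fold (2.66 to 4.29). The 10 measured NURF and ISWI subunits had a median of -0.60 at percentile 1.56, with 0 past over all genes and 0 adjusted over the list alone. Pan-luminal and hormone-sensing genes also had 0 members past, over all genes and adjusted over the list alone, at medians of 0.32 and 0.03. G2 and M phase genes had a median of -1.10 (-1.33 with genes at 0 placed at the floor) at percentile 1.74, with 0 of 20 past over all genes and 0 adjusted over the list alone. Of the lists for cells other than epithelium, none had a member past over all genes. Fibroblast markers had a median of 0.32 at percentile 62.6, and adipocyte markers, with 5 measured, one of -1.96 at percentile 3.1, while the 1 measured erythrocyte marker was higher adjusted over the list alone.

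**Figure D1:**
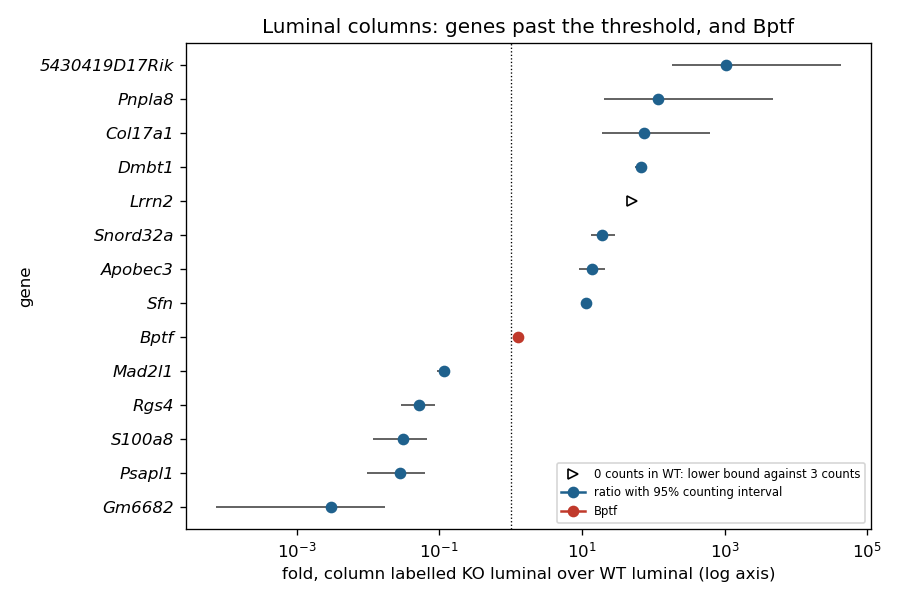
Fold of the column labelled KO luminal over WT luminal (log axis) for the 13 genes past an adjusted p of 0.05 and for Bptf, with lines for the 95% counting interval and an open arrow for the lower bound of Lrrn2, which had 0 counts in WT. The 8 higher genes lie right of 1 and the 5 lower genes left of it, while Bptf sits at 1.27.

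The comparison of the basal columns was made to ask the same of myoepithelial cells, and their conflicting names leave the genotype of each side open. Nrcam, a neuronal cell adhesion molecule, had 756 counts in the smaller column and 28 in the larger (37.8-fold, 25.9 to 57.3). Esr1, the oestrogen receptor that marks hormone-sensing luminal cells, had 713 against 30 (33.3-fold, 23.1 to 49.7). The tight junction protein Cldn4 had 4 counts in the smaller column and 374 in the larger (66.8-fold, 25.9 to 246), and Apobec3 had 1 against 237 (169-fold, 30.1 to 6714). These 4 genes, 2 on each side, were the ones past an adjusted p of 0.05 among 14595, with adjusted p from 0.00193 to 0.0318 by Benjamini-Hochberg adjustment of the DESeq p-values in the authors' deposited table. Hormone-sensing genes as a list did not follow Esr1. Their median log2 fold, smaller over larger, was -0.55 at percentile 18.2, with 1 of 14 higher over all genes and 1 adjusted over the list alone. Foxa1 and Cited1 had 0 counts in the smaller column. On the common scale Esr1 was at 947 there, 434 in KO luminal and 320 in WT luminal cells. A further view by size alone found 203 genes at least 4-fold higher and 125 at least 4-fold lower in the smaller column among 5691 with a mean value of 50 or more. That balance depends on the rule, since an edgeR exact test with an assumed dispersion of 0.16 called 114 higher and 236 lower. Another scale, the totals without Rn45s, would lower each log2 fold of this comparison by 0.17.

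Fibroblast genes stood lower in the smaller basal column. Over all genes 0 of 12 markers passed and adjusted over the list alone 3 were lower, and the list's median of -2.57 lay below that of each of the 10000 random lists. The matrix proteoglycan Dcn had 98 counts against 1349 (9.83-fold lower, 8.01 to 12.2) and Lum 3 against 160 (38.1-fold, 12.8 to 187). Dcn was read in the sorted luminal columns too, with 868 counts in WT and 1360 in KO. Schwann and nerve markers were at a median of -2.34 (percentile 0.81), or -1.36 with genes at 0 placed at the floor. Pericyte markers were at -1.47 (4.4) and endothelial markers at 0.05 (77.1). Skeletal muscle markers were at 2.33 (99.5), or 1.65 with genes at 0 placed at the floor. Each of these lists had 0 past over all genes and 0 adjusted over the list alone. Interferon response genes also stood lower in the smaller column, with a median of -2.48 at percentile 0.01 (-2.13 with genes at 0 placed at the floor), 0 of 23 past over all genes and 2 lower adjusted over the list alone. The RNA sensor Ddx58 was 17.8-fold lower (8.44 to 44.8) and Oasl2 11.1-fold lower (6.98 to 18.7). Some other lists lay on the other side. Immediate early genes had a median of 1.01 at percentile 99.96, with 0 of 21 past over all genes and 1 higher adjusted over the list alone. By level, whether or not past that adjustment, Fosl1 was at 9.60-fold (6.96 to 13.6) and Ier3 at 4.20-fold (3.88 to 4.56). Glycolysis and hypoxia genes were at 1.16 (percentile 99.97), ribosomal proteins at 0.89 (99.9) and Myc targets of ribosome biogenesis at 0.83 (99.8), with 0 past over all genes and 0 adjusted over the list alone in each, beside the higher Rn45s share of the same column. S phase and G2 and M phase genes had medians of -0.63 and -2.11 (-0.68 and -1.39 with genes at 0 placed at the floor) at percentiles 20.9 and 13.8, also with 0 past over all genes and 0 adjusted over the list alone. The basal identity list was at 0.49 (percentile 97.5), with 0 of 24 past over all genes and 0 adjusted over the list alone, Krt14 at 3.68-fold (3.50 to 3.86) and Cnn1 at 4.31-fold (3.93 to 4.72).

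Bsecs were set against both basal columns to place this population beside the basal lineage. Several smooth muscle contractile genes were among the calls lower in Bsecs. Myosin heavy chain Myh11 had 19 counts in Bsecs, 4223 in the larger basal column (202-fold lower, 129 to 336) and 3463 in the smaller (231-fold, 148 to 385). Calponin Cnn1 was lower 142-fold (55.4 to 525) against the larger and 612-fold (239 to 2250) against the smaller column, and the enteric actin Actg2 170-fold (46.7 to 1409) and 444-fold (122 to 3672). Mme, with 1 count in Bsecs, fell 1972-fold (354 to 77918) and 1321-fold (236 to 52208), and the Wnt receptor Fzd7 99.6-fold (60.2 to 178) and 52.3-fold (31.5 to 94.04). Some luminal genes were among the higher calls. Keratin Krt7 had 1222 counts in Bsecs and 6 in the larger column (224-fold, 103 to 612), the EGF receptor ligand Areg 412 against 1 there (453-fold, 80.9 to 17943) and 0 in the smaller column (at least 108-fold), and the hormone-sensing factor Foxa1 216 against 2 (119-fold, 32.5 to 987) and 0 (at least 56.7-fold). Krt7 was not past the test against the smaller column. On the common scale it was at 1288 in Bsecs, 47.8 in the smaller and 5.77 in the larger basal column.

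Counted over all genes, 34 were higher and 38 lower in Bsecs than in the larger basal column among 14986, and 52 higher and 52 lower than in the smaller among 13698, by Benjamini-Hochberg adjustment of the DESeq p-values in the authors' deposited tables. Of the calls, 27 higher and 30 lower genes were shared, where independent lists would share 0.133 and 0.149. Both comparisons use the same Bsecs column, so part of that sharing may come from it. Simulated columns with no effect shared 0 in 100 draws over 13300 genes, but they gave nearly no calls at all (a mean of 0.04 per comparison), so that value sets no expectation for columns that differ. Beyond the lineage genes, those higher than the larger column included the protease Adam8 (313-fold, 134 to 966), the actin regulator Anln (333-fold, 142 to 1027), the interferon-inducible Ifi202b (346-fold, 135 to 1272), Tubb2b (569-fold, 102 to 22505), Msx2 (436-fold, 77.7 to 17248) and Basp1 (321-fold, 88.5 to 2659). Against the smaller column, the wound keratin Krt6a had 4664 counts against 3 (1224-fold, 419 to 5939), Adam8 1424 against 1 (1121-fold, 201 to 44327), the activin subunit Inhba 1067 against 1 (840-fold, 150 to 33222), the receptor Fgfr3 903 against 1 (711-fold, 127 to 28120) and the EGF receptor ligand Epgn 1749 against 4 (344-fold, 134 to 1265). Genes lower against both columns included the protease Adam19 (670-fold, 120 to 26499, and 1015-fold, 182 to 40121), the ectonucleotidase Entpd1 (433-fold, 148 to 2102, and 338-fold, 115 to 1641) and the TGF-beta co-receptor Tgfbr3 (320-fold, 109 to 1554, and 295-fold, 101 to 1434). Of the genes past the test, 14 against the larger and 47 against the smaller column had 0 counts on 1 side.

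Of the basal identity list, 5 of 24 members fell against the larger basal column and 0 rose over all genes, and 9 were lower and 1 higher adjusted over the list alone, at a median of -2.62. Against the smaller column 6 fell and 0 rose, and 12 were lower and 1 higher adjusted over the list alone, at a median of -3.02, and both medians lay below those of all 10000 random lists. The keratins of this list were not among the calls. Krt14 was 4.29 times its larger-column value (4.10 to 4.503), Krt17 2.46 times and Krt5 1.87 times, and 1.17 times (1.13 to 1.21), 0.657 times (0.632 to 0.683) and 1.03 times their smaller-column values, none past the test, while smooth muscle actin Acta2 had 137 counts against 12085 in the larger column (80.2-fold lower, 67.8 to 95.6), also not past it. Of 23 pan-luminal genes, 3 rose against the larger column (Areg, Krt7 and Ehf) and 2 against the smaller (Areg and Cldn7), with 6 higher adjusted over the list alone in each, at medians of 2.69 and 2.70. Luminal progenitor and alveolar genes had 0 past over all genes in either comparison, with a median of 0.00 against the larger column (1 of 16 higher and 3 lower adjusted over the list alone) and of -2.21 against the smaller, below all 10000 random lists (1 of 20 higher and 0 lower adjusted over the list alone). Hormone-sensing genes gave 2 of 16 higher in each, Foxa1 and Cited1, and 6 higher adjusted over the list alone in each, with 0 lower against the larger column and 1 against the smaller. In the list of stem and repopulating cell genes, Sox10 fell 123-fold (33.6 to 1019) and 186-fold (51.0 to 1543) and 18 of 19 members did not pass in either comparison, with 3 lower against the larger column and 2 against the smaller adjusted over the list alone. Sox10 is also on the list of nerve sheath markers, where it was the 1 member past the test, over all genes and adjusted over the list alone. The median of that list was -3.07 (percentile 0.34) against the larger and -1.45 (4.97) against the smaller column. With genes at 0 placed at the floor it was -2.32 and -1.73. Fzd7 was the 1 Wnt pathway gene past the test in each comparison, with 1 higher and 3 lower adjusted over the list alone. The chemokine Ccl20 was the 1 inflammatory gene past it, 118-fold higher (32.2 to 978) and at least 56.2-fold higher, with 2 and 1 higher adjusted over the list alone. The laminin chain Lama1 was the 1 basement membrane gene past it against the smaller column (at least 80.8-fold lower), with 1 lower adjusted over the list alone. Fibroblast markers had a median of -2.23 against the larger column and 0.13 against the smaller, with 0 past over all genes and 0 adjusted over the list alone. Pericyte markers were at -2.66 (percentile 0.83) and -1.03 (18.4), with 0 past over all genes and 0 adjusted over the list alone. Endothelial markers were at -2.64 (0.06) and -2.46 (0.155), or -1.30 and -1.34 with genes at 0 placed at the floor, with 0 past over all genes and 1 lower against the larger column adjusted over the list alone. The highest pericyte marker of the larger basal column, Mcam, had 103 counts there and the highest endothelial one, Cdh5, 117, where Acta2 had 12085.

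**Figure D2:**
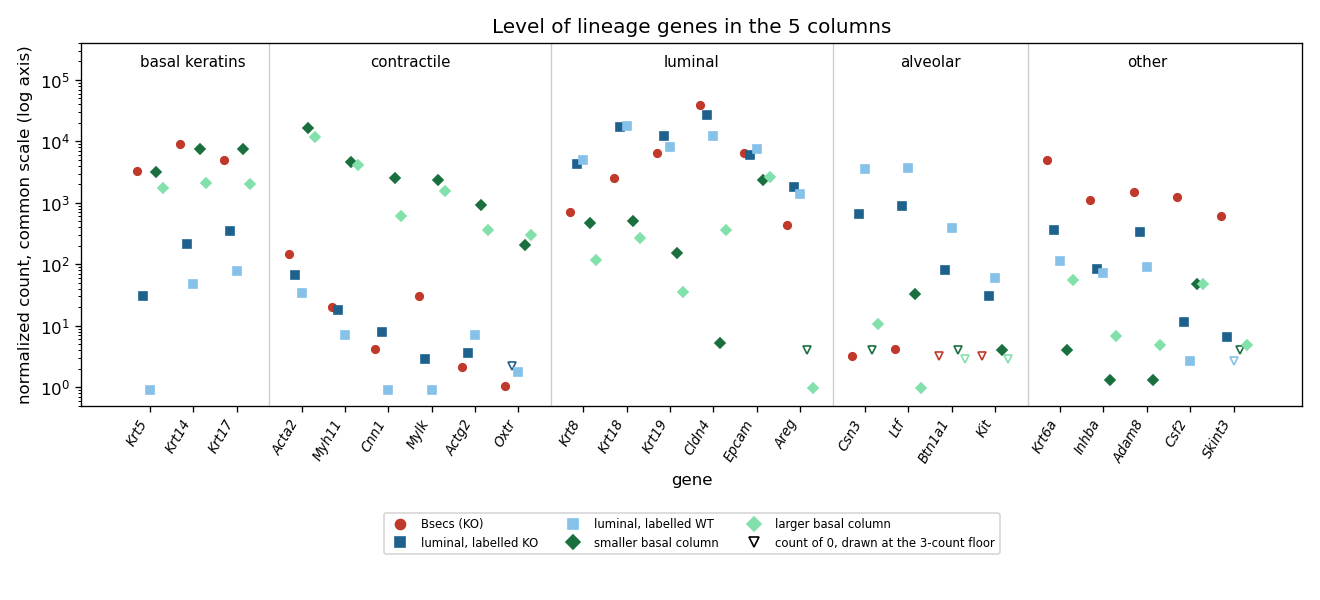
Normalised counts (log axis) of lineage genes in the 5 columns on a common scale, 1 point per gene and column, with open triangles at the 3-count floor for genes with 0 counts. Bsecs had Krt5 at 3307 and Krt14 at 8945, beside the basal columns, Cldn4 at 39058, beside the luminal columns, and Acta2 at 144 where the basal columns had 16612 and 11621.

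Against WT luminal cells, the calls higher in Bsecs included keratins and Col17a1, and milk protein genes were among the calls lower than in both luminal columns. Krt5 rose from 1 count in WT luminal cells to 3139 in Bsecs (3863-fold, 693 to 152644), Krt15 450-fold (218 to 1119), Col17a1 872-fold (241 to 7207), P-cadherin Cdh3 267-fold (73.5 to 2212) and the epidermal galectin Lgals7 260-fold (126 to 647). The hyaluronan synthase Has2 rose against both luminal columns, 164-fold (83.1 to 382) over the column labelled KO luminal and 1079-fold (193 to 42681) over WT. The casein Csn3, with 3 counts in Bsecs, fell 200-fold (68.2 to 972) and 1065-fold (364 to 5165), and lactoferrin Ltf 201-fold (78.4 to 740) and 838-fold (327 to 3077). The membrane mucin Muc4 fell 286-fold (78.9 to 2365) and 968-fold (268 to 7995), and the lipoxygenase Alox15 776-fold (139 to 30676) and 670-fold (120 to 26508).

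In counts, 1 gene was higher and 5 were lower in Bsecs than in the column labelled KO luminal among 14800, and 17 higher and 13 lower than in WT luminal cells among 14304, by Benjamini-Hochberg adjustment of the DESeq p-values in the authors' deposited tables. The balance against WT luminal cells depends on the rule, since an edgeR exact test with an assumed dispersion of 0.16 called 747 higher and 1226 lower. The 6 genes of the KO luminal comparison, with Nrxn3 (232-fold lower, 90.3 to 851) beside those above, had adjusted p of 0.0256 to 0.0429 from the authors' deposited table, and 0 of them pass at 0.01. Has2 and 4 of the lower genes were called in both comparisons, where independent lists would share 0.00124 and 0.00473, and part of that may come from the shared Bsecs column. The difference between the 2 luminal comparisons was not tested as such. Nor do the numbers of calls rank the columns by closeness to Bsecs, since their order turned by size alone. With a mean of at least 50 and a counting interval excluding 1, 1102 and 1197 genes were at least 4-fold apart from KO and WT luminal cells. Against the larger and smaller basal columns 914 and 860 were. Higher against WT luminal cells were also the actin bundler Fscn1 (1228-fold, 220 to 48564), Ltbp4 (782-fold, 140 to 30917), Ifi202b (516-fold, 176 to 2506) and the cytokine Csf2 (484-fold, 165 to 2349). Lower were also Mme (375-fold, 67.0 to 14858), the kallikrein Klk10 (322-fold, 88.9 to 2665), the nucleoside transporter Slc28a3 (275-fold, 75.7 to 2272), Lcmt1 (353-fold, 63.0 to 13960), Arhgef6 (162-fold, 55.2 to 788) and the histone gene Hist1h2bc (135-fold, 65.3 to 337). A scale from totals without Rn45s would lower the log2 folds by 0.21 and 0.32.

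Of 24 basal identity genes, 0 passed against KO luminal and 6 were higher adjusted over the list alone, at a median of 2.83, and against WT luminal 3 rose and 1, Mme, fell, with 8 higher and 1 lower adjusted over the list alone, at a median of 3.06. Krt5 was at 112-fold (82.7 to 156), Krt14 at 42.7-fold (38.1 to 48.1) and Krt17 at 15.0-fold (13.7 to 16.6) over KO luminal cells. Luminal progenitor and alveolar genes had medians of -4.18 (-3.38 with genes at 0 placed at the floor) and -4.32. Of 19 members 2 fell against KO luminal and of 20 members 3 fell against WT luminal, Btn1a1 by at least 118-fold, with 5 and 6 lower adjusted over the list alone. Pan-luminal genes had medians of -1.24 and -0.86 with 0 past over all genes and 2 and 1 lower adjusted over the list alone. By level, whether or not past that adjustment, the mucin Muc1 was 187-fold below KO luminal (51.4 to 1545), Krt18 6.42-fold (6.16 to 6.70) and Krt8 5.95-fold (5.49 to 6.46). Hormone-sensing genes had medians of -1.41 and -1.90 with 0 past over all genes and 0 adjusted over the list alone. Basement membrane genes had medians of 1.32 and 2.89, with 0 and 1 (Col17a1) higher over all genes and 1 and 6 adjusted over the list alone, and tenascin Tnc stood at 29.0-fold (25.9 to 32.5) over KO luminal cells. Myc targets of ribosome biogenesis had medians of 1.87 and 1.25 at percentiles 100 and 99.8, with 0 of 21 past over all genes and 0 adjusted over the list alone, Npm1 at 6.02-fold (5.71 to 6.34) and Ncl at 5.09-fold (4.91 to 5.27) over KO luminal cells, beside the 32.2% share of Rn45s in Bsecs. That lean did not hold against both basal columns. The same list was at 0.65 (percentile 96.2) against the larger and -0.07 (21.7) against the smaller basal column, with 0 past either adjustment. In the senescence list, Igfbp3 was the 1 member past the test, at least 161-fold higher than in WT luminal cells, with 1 higher and 1 lower adjusted over the list alone. Fibroblast markers were at medians of 3.06 and 2.94 (2.65 and 1.88 with genes at 0 placed at the floor) with 0 past over all genes and 0 adjusted over the list alone. Those medians came from genes of few counts, while Dcn was 4.82-fold lower in Bsecs (4.14 to 5.65) than in KO luminal cells. Against KO and WT luminal cells, pericyte markers were at medians of 2.78 and 1.19 (percentiles 99.6 and 90.4). Endothelial markers were at -2.65 and -1.96 (3.5 and 8.5). Macrophage and dendritic cell markers were at -3.02 and -2.92 (3.3 and 5.3). Schwann and nerve markers were at -1.54 and -2.68 (16.1 and 1.3). With genes at 0 placed at the floor these medians were 3.39 and 0.84, -2.73 and -0.92, -3.19 and -1.47, and -0.91 and -0.70. These lists had 5 to 8 measured genes and 0 past over all genes. Adjusted over the list alone, 1 pericyte gene was lower than in KO luminal cells and 0 others passed.

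No gene was past the test in the same direction in all 4 Bsecs comparisons among 12874 measured in each. Only the 1 higher and 5 lower calls against KO luminal cells could have qualified, so this 0 says little about Bsecs. By size alone, 43 genes were at least 4-fold higher and 89 at least 4-fold lower in Bsecs than in each other column, of 6455 with a mean of at least 50. The same rule gave 8 and 17 for the column labelled KO luminal, 13 and 76 for WT luminal, 26 and 101 for the smaller basal and 16 and 41 for the larger basal column. Each luminal or basal column has a partner of its own lineage among the other 4 and Bsecs has none, so these numbers are not alike. The genotype difference in basal cells was also set against that in luminal cells, over 9516 genes, with a standard error taken from each p-value of the authors' deposited tables. With the smaller basal column as knockout 3 genes differed at an adjusted p under 0.05 (Apobec3, Pnpla8 and the predicted gene Gm6682), and with the larger one 5 did (Snord32a, Sfn, Ncald, Col17a1 and Esr1). The genes called in both tables numbered 0 on the same side with the smaller basal column as knockout and 1, Apobec3, with the larger, where independent calls would give 0.00109 or fewer per direction.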

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

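Of the tests in this part, the correlation and the same-side shares by fold size across genes, and the comparison of Apobec3, Pnpla8 and Gm6682 levels, were chosen only after the results they bear on had been seen.

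The difference between the genotype effects in basal and in luminal cells passed an adjusted p of 0.05 for 3 genes when the basal columns are named as in the basal table, so that the smaller one is the knockout. The log2 fold in basal cells minus that in luminal cells was -11.18 for Apobec3 (SE 1.89, adjusted p 3.30e-05), 13.24 for the predicted gene Gm6682 (SE 2.32, adjusted p 5.24e-05) and -11.12 for Pnpla8 (SE 2.35, adjusted p 0.00730), by Benjamini-Hochberg adjustment over 9516 genes of an approximate test built on the DESeq p-values of the authors' deposited tables. With the other naming these 3 genes do not pass and 5 others do.

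The first pattern is the pair of opposite names on the basal columns. Of 38 genes with an unadjusted p under 0.05 in both the luminal and the basal table, 52.6% (exact 95% interval 35.8 to 69.0) lay on the same side with the larger basal column as knockout and 47.4% (31.0 to 64.2) with the smaller, so neither a header exchange in the basal table nor one in both Bsecs tables can be excluded and the namings cannot be told apart by that test. Across 4969 genes with a mean of at least 50 the log2 folds of the luminal and the basal table had r = 0.18 and rho = 0.20 with the smaller column as knockout (r = 0.30 over 1710 genes of at least 200 and 0.32 over 185 of at least 1000), with signs reversed for the larger, though genes are not independent. Of genes at least 2-fold apart in both tables, 225 of 318 (70.8%, 65.4 to 75.7) lay on the same side with the smaller column as knockout, as did 10 of 13 at 4-fold and 4 of 5 at 8-fold. That interval treats the genes as independent, which they are not, and does not measure spread between libraries. The correlation and these shares may point to the smaller column as the knockout if the luminal columns are labelled correctly, and to the larger one if they are exchanged, which the conflict in the labels of the KO luminal libraries leaves open. Other values lean against the smaller column on the same condition. Interferon response genes had a median log2 fold of 0.95 in KO over WT luminal cells and -2.48 in the smaller over the larger basal column. Apobec3, Pnpla8 and Gm6682 put every KO column on 1 side of every WT column only with the larger column as knockout. The basal identity list goes with the smaller one, at 1.24 and 0.49. These examples were picked after their values had been seen. Also, the KO luminal and smaller basal columns shared a higher Rn45s percentage (15.9 and 16.2 against 10.6 and 9.76), so a library property in common stays open and so does the naming.

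The second pattern is that Apobec3, Gm6682 and Pnpla8 go opposite ways in luminal and basal cells if the smaller basal column is the knockout, while they go the same way if the larger one is. A difference of genetic background between knockout and wild-type mice might give such genes, since Apobec3 is known to differ between inbred strains, and it would place every KO column on 1 side of every WT column. With the larger basal column as knockout the nearest KO and WT columns were 2.16-fold apart on the common scale (Bsecs 55.8, WT luminal 25.9), and with the smaller basal column they overlapped, at a ratio of 0.0718. Apobec3 did not meet the bound of 4-fold set for this test. With the larger basal column as knockout the other 2 genes did separate KO from WT columns by more than 4-fold. Pnpla8 was at 48.5 in Bsecs, 107 in KO luminal and 102 in the larger basal column. It was at 0.893 in WT luminal and 5.31 in the smaller basal column. Gm6682 was at 9.48, 0.723 and 2.88 against 235 and 83.6, in that order. These 3 genes were picked for their luminal and basal folds, and several of these counts are near 0. They are too few to exclude a background difference elsewhere in the genome, so that bound was wrong as an exclusion. This stays open together with the naming. An effect of Bptf loss that differs between cell types stays open too, as untested.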

How the results depend on the processing

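The alternatives by unadjusted p, exact binomial test, edgeR, fold size, other scales and exchanged basal names were chosen after seeing the data. Counts stand in the order smaller against larger basal (4 genes as reported), KO against WT luminal (13), and Bsecs against larger basal (72), KO luminal (6), smaller basal (104) and WT luminal (30). At an adjusted p under 0.01 they were 2, 5, 20, 0, 42 and 14. At 0.10, those that moved by over 1.5 times were 8, 22, 116 and 27 for the first 4. Adjusting over genes with a mean of at least 50 gave 9, 21, 135, 27, 169 and 48, and with a mean of at least 10 gave 8 for the basal and 13 for the Bsecs against KO luminal comparison, since fewer genes were tested. Bonferroni adjustment gave 5, 11, 1, 28 and 5 for the last 5. Requiring counts in both columns left 42 of the 104 calls against the smaller basal column. Unadjusted p-values under 0.05 numbered 451, 551, 691, 565, 673 and 614. An exact binomial test, which takes counting error as the only error, called 6696, 7177, 7594, 8299, 7150 and 8234. An edgeR exact test with an assumed dispersion of 0.16 called 350, 226, 1275, 1644, 1400 and 1973, so the number of calls rests on the spread assumed, which these files cannot give. A rule of at least 4-fold, a counting interval excluding 1 and a mean of at least 50 gave 328, 289, 914, 1102, 860 and 1197. By edgeR and by this rule Bsecs had more genes apart from the luminal than from the basal columns, the reverse of the calls as reported. The totals of calls therefore do not rank the comparisons.

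Genes whose genotype effect differed between basal and luminal cells numbered 3 as reported, 1 with a mean of at least 50 in both tables and 5 with exchanged basal names. Genes called on the same side in both numbered 0, 1 with exchanged names and 18 by unadjusted p. Genes set apart in Bsecs numbered 0, and 132 by the 4-fold rule. Beyond the thresholds themselves, the cause of these moves was not tested. Totals without Rn45s in place of the authors' size factors moved the median log2 fold by -0.17, -0.08, -0.36, -0.21, -0.20 and -0.32, and TMM by between -0.12 and 0.11. Of 1215 values of 102 results for named genes, 1092 kept their direction and side of the threshold, 118 lost the call (69 under Bonferroni, 49 at 0.01), 4, all Bptf under the binomial test, passed where they had not, and 1 reversed, the log2 fold of Bptf in Bsecs over WT luminal cells (0.31, -0.0135 with totals without Rn45s), which was not a call. No paired analysis was possible because the tables hold 1 column per group, and for the same reason DESeq2, an edgeR quasi-likelihood fit with and without a filter on low counts and leaving out replicates were not run. Another pseudocount was set for values per library only, of which there are 0, and list medians were not recomputed with it. Depth limits genes near 0, where folds are bounds or have wide intervals.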

Other observations

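The tests of the Bsecs pattern in this part, and the subsets of contractile and keratin genes they use, were chosen only after the levels had been seen.

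Some genes set Bsecs apart by level. On the common scale the wound keratin Krt6a was at 4914 normalised counts in Bsecs and at most 356 elsewhere, Krt16 at 4832 and at most 244, Krt15 at 2694 and at most 92.5, the galectin Lgals7 at 1556 and at most 48.1, and the serpin Serpinb2 at 1243 and at most 79.8. Secreted and matrix factors followed, with Timp3 at 24554 against at most 1748, tenascin Tnc at 6534 against 514, the cytokine Csf2 at 1242 against 47.8 and the activin subunit Inhba at 1124 against 83.1. The immunoglobulin-like Skint3 was the farthest apart, at 621 against 6.50. Among genes lower in Bsecs than in each other column were Igfbp5 (80.1 against at least 1160), the lipocalin Lcn2 (644 against at least 8834), the prostaglandin synthase Ptges (17.9 against at least 245), the endocytic adaptor Dab2 (2.11 against at least 129) and Sox10 (2.11 against at least 60.7). These genes were picked by size, at least 4-fold from each column, with no test over replicates.

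Of other genes, Ccnd2, a D-type cyclin, was at 1613 in Bsecs, 413 and 559 in the basal columns, 12.3 in KO luminal and 0 in WT luminal cells, and Wnt7b at 731 in Bsecs, 677 and 474 in the luminal and 29.2 and 25 in the basal columns. Pecam1, an endothelial marker, had 85 counts in the larger basal column, 15 in the smaller and 0 in Bsecs, while Flt1 of the same list was at 189 normalised counts in Bsecs and at most 32.1 elsewhere. The leukocyte marker Ptprc had at most 3 counts in any column.

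The third pattern is the mix in Bsecs of keratins Krt5, Krt14 and Krt17, luminal genes such as Cldn4 and contractile RNA far below that of basal cells. Other members of the basal identity list were low in Bsecs too, with Sparc at 135 against 1933 and 2379 in the basal columns and Vim at 119 against 657 and 668. Nor were all luminal genes high, as Muc1 was at 2.11 in Bsecs and 42.5 and 13.5 in the basal columns. The pan-luminal list had medians of 2.69 and 2.70 against the larger and smaller basal columns, and of -1.24 and -0.86 against KO and WT luminal cells. Luminal cells mixed with cells like those of the basal columns would bring contractile RNA at no lower a share than keratins. The tables argue against such a mixture, since the highest of 9 contractile genes, Myl9, stood at 14.6% of the larger basal column (median 1.24%) and the lowest of the 3 keratins, Krt5, at 187%. Against the smaller column these were 8.35% (median 0.869%) and 66.2% (Krt17), and 61.6% after subtraction of the higher luminal level of each keratin, so the gap was narrower there and kept its direction. No common factor, such as 1 from the Rn45s share, gives that either, as the keratin ratios exceeded the contractile ones by at least 12.8-fold against the larger and 7.93-fold against the smaller column. The keratins and contractile genes used here also define the pattern, so this covers only mixtures with cells like those of the basal columns. Other cells with keratins and little contractile RNA were not tested as a source. Whether loss of Bptf or the gate of this population gives the pattern cannot be told apart, as the number of wild-type Bsecs columns analysed here is 0.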
